A study of Homo sapiens with 6 samples.

How the data were processed

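RNA from K562 cells was measured on 6 Affymetrix GeneChip Human Genome U133 Plus 2.0 arrays. K562 is an established human myeloid leukaemia line that carries the BCR-ABL fusion and expresses embryonic and fetal globins. ICL670 (deferasirox) is an oral iron chelator. Per the labels, 2 arrays came from untreated cells, 2 from cells given ICL670 at 10 uM and 2 from cells given ICL670 at 50 uM, with an incubation of 16 h. Arrays were grouped by their titles. For replicate 1 at 10 uM the treatment field reads as a mock treatment, while its title and source name give 10 uM; it was kept at 10 uM. The labels number the arrays of a group without saying that they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

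The deposited values are intensity signals on a linear scale, 1 per probe set and array. Per the labels' protocols, total RNA was extracted with a spin column kit, labelled with biotin by the one-cycle method and hybridised. The series text names GeneSifter for the authors' statistics; the test, and the algorithm that summarised and scaled the probe signals, are not given in the sources used here. The deposited intensity values had been scaled: leaving out the lowest and highest 2 percent of probe sets, the mean signal was 500.1 on each of the 6 arrays, and these means differed by at most 0.00104 percent, against a tolerance of 5 percent. They were therefore used as deposited and taken to log2(signal + 16). A fold change on this scale understates the change of dim genes. The number of arrays limits the precision.

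Of 54675 probe sets, 62 control probe sets were left out of the tests. The platform annotation gave 1 gene symbol for 41091 of the others, several symbols for 1801 and none for 11721. Of the first kind, 41037 were matched by gene number to the GRCh38.p14 RefSeq gene table to update symbols. No genome build is named for the files, so no coordinates are given. A probe set was kept if its mean log2 value over the 6 arrays exceeded the median of the non-control probe sets (6.24, a signal of 59.5). Each gene was represented by 1 kept probe set with a single symbol, preferring sets whose name does not end in _x_at and then the highest mean. This left 11903 genes, 407 of them through an _x_at set, and 5931 genes had more than 1 kept probe set. Of the named genes, 66 had other kept probe sets, and for 1, GDF15, another one was called with the opposite sign. Probe sets can also bind transcripts of close paralogs.

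Differences were tested in R 4.3.3 with limma 3.58.1: 1 mean per group fitted over all 3 groups, which share 1 estimate of the spread, eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the 11903 genes of each of 3 comparisons. A gene is called higher or lower at an adjusted p under 0.05. The fit had 3 residual and 7.40 prior degrees of freedom, and the median standard error of a log2 fold change was 0.13. Values are mean signal ± SD over 2 arrays; log2 fold changes are ± standard error. The fit was tried on simulated data for the comparison of 50 uM with untreated, with 11903 genes. It called 41.8% of 67 genes changed by 0.5 on the log2 scale, 77.6% of 67 changed by 1 and 98.5% of 66 changed by 2. Of 11703 unchanged genes it called 11. The adjusted p depends on the share of changed genes, which was far smaller there than in the data, where 5597 genes were called at 50 uM. These rates therefore do not carry over to the data.

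Gene lists (26) were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The estimate rests on 3 residual degrees of freedom. At both doses against untreated no list held with an estimated correlation, and between the doses 4 did. The estimate lay below the preset 0.01 for some lists, such as hypoxia (-0.0032), cholesterol synthesis (-0.0447) and immediate early genes (-0.0387). For these, a larger p does not come from a larger correlation among their genes. It lay above 0.01 for others, such as the integrated stress response (0.142) and the respiratory chain (0.198). The lists, the rule for named genes, the tests of the comparisons and the alternatives, except those named below, were chosen before the data were examined. The rule names, per comparison, the 10 largest rises and 10 largest falls among called genes that moved the same way in all 4 pairs of arrays, up to 4 members per list with the smallest p at 50 uM, and a fixed set of genes in any case. Of this set, FTH1 is not analysed here and HMOX1 lay below the filter. A further 7 lists were chosen after seeing the data. So were the alternatives of testing all probe sets above the filter and of setting each dose against its own untreated array. The further lists were not part of the 26. The 7 are interferon-stimulated genes, RNA polymerase I and III subunits, tubulins, cytosolic and mitochondrial aminoacyl-tRNA synthetases, and the amino acid genes and the regulators of the integrated stress response list. Alternatives covered the scaling, pseudocounts of 1 and 64, the filter, the choice of probe set, the variance model, the samples in the fit, the replicate number as a block, each array left out in turn and a minimum log2 fold change of 1. Figures were drawn with matplotlib 3.10.9.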

Results

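Transcript levels were compared in K562 cells left untreated or given the iron chelator ICL670 for 16 h at 10 or 50 uM, with 2 arrays per group and 54675 probe sets per array. The median signal was between 62.5 and 71.3 per array. Over the 11903 genes tested, the log2 signals of the 2 arrays of a group correlated across genes at Pearson r = 0.988 untreated, 0.986 at 10 uM and 0.984 at 50 uM. Arrays of different groups correlated at 0.948 to 0.973. Replicate 1 at 10 uM was thus closer to the other 10 uM array than to either untreated array. This argues against the mock treatment that its treatment field gives. The ratio of 3' to 5' signal of ACTB, a sign of RNA quality, was 1.5 ± 0.087 untreated, 1.66 ± 0.0094 at 10 uM and 1.70 ± 0.035 at 50 uM (SD, n = 2 each). That of GAPDH was 1.30 ± 0.062, 1.33 ± 0.028 and 1.30 ± 0.0088. A control probe set for the middle of 18S ribosomal RNA read 7535 in untreated replicate 2 and between 1261 and 3351 on the other 5 arrays.

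The comparison of 50 uM with untreated asks which transcripts change at the higher dose. INHBE, an activin subunit, rose from a signal of 69.2 ± 13.4 to 1877 ± 98.3 (SD, n = 2 each, as for all signals). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 7.15 ± 8.13, near background, to 482 ± 104. DDIT4 (REDD1), an inhibitor of mTORC1, rose from 1121 ± 192 to 16759.8 ± 64. The log2 fold changes of INHBE and DDIT4 were 4.48 ± 0.16 and 3.89 ± 0.09, and the limma adjusted p-values (Benjamini-Hochberg) of INHBE, PDK4 and DDIT4 were 2.08e-08, 1.45e-06 and 1.67e-09. CHAC1, ATF3, YPEL3, FAM107B, CXCL8, PHGDH and DDIT3 completed the 10 largest rises, which these 3 led, with log2 fold changes from 3.25 to 3.76. Untreated signals of PDK4, CHAC1 (42.1 ± 25.6) and YPEL3 (58.6 ± 22.9) were below the filter level of 59.5, so the sizes of their rises depend on the 16 added before taking logs and their ranks are uncertain. The largest falls were NEFH, a neurofilament subunit (1839 ± 149.6 to 160.2 ± 14.2, log2 fold change -3.40 ± 0.13), PRG2 (-2.93), DHRS2 (-2.91), CYP26A1 (-2.87) and POLR1G, a subunit of RNA polymerase I (-2.78). The fatty acid binding protein FABP5, SH2D1B, GPATCH4, TRIM14 and WNT10B followed, from -2.65 to -2.13. At 50 uM CYP26A1 read 15.2 ± 15.3 and WNT10B 22.3 ± 7.21, below the filter level, so the sizes of their falls are uncertain. In all, 2835 genes were called higher and 2762 lower, 5597 together (47.0% of the genes tested), and 660 and 416 of them changed at least 2-fold. With the arrays centred on their medians the split was 2202 higher and 3220 lower.

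Genes of the integrated stress response, which follows phosphorylation of eIF2 and acts through ATF4, rose at 50 uM. Of 27, 24 were higher and 0 lower, with the same count adjusted over the list alone. The median log2 fold change was 1.96 (limma camera adjusted p = 4.48e-18; adjusted p = 0.0873 with an estimated correlation). Asparagine synthetase ASNS went from 2839 ± 19.7 to 22828 ± 612, the serine synthesis enzyme PHGDH from 547 ± 21.6 to 5621 ± 120.3, and the transcription factor ATF3 from 267 ± 10.8 to 3303 ± 110.3. Among endoplasmic reticulum chaperone and stress genes 14 of 17 were higher and 0 lower, the same adjusted over the list alone. The median was 0.72 (adjusted p = 6.86e-07; adjusted p = 0.0873 with an estimated correlation). The chaperone HSPA5 went from 12673 ± 542 to 32328 ± 819.8. HERPUD1, DNAJB9 and MANF had log2 fold changes of 2.11 ± 0.08, 1.62 ± 0.11 and 1.34 ± 0.08. Genes of the hypoxia response rose as well, 21 of 29 higher and 0 lower (22 and 1 adjusted over the list alone). Their median was 0.94 (adjusted p = 9.43e-09; adjusted p = 0.0873 with an estimated correlation). VEGFA, an angiogenic growth factor, went from 5468 ± 113 to 16978 ± 616, and NDRG1 from 158 ± 7.07 to 816 ± 69.4. The mitophagy receptors BNIP3L and BNIP3 and the glucose transporter SLC2A3 had log2 fold changes of 1.99 ± 0.08, 0.78 ± 0.06 and 1.17 ± 0.05. Iron and 2-oxoglutarate dependent oxygenases were higher in 13 of 27 and lower in 2, the same adjusted over the list alone. This list had a median of 0.31 (camera adjusted p = 0.0213, and adjusted p = 0.158 with an estimated correlation). In it were the collagen hydroxylase subunit P4HA1 at 1.73 ± 0.09 and the histone demethylase KDM3A at 1.17 ± 0.08. The hypoxia list shares DDIT4 and STC2 with the integrated stress response list and was not tested without them. The oxygenase list shares P4HA1, P4HA2, KDM3A, EGLN1 and EGLN3 with the hypoxia list and was not tested without them. Without untreated replicate 2 its adjusted p was 0.0583.

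Cholesterol synthesis genes rose, 12 of 13 higher and 0 lower, the same adjusted over the list alone. The median change was 0.75 (adjusted p = 1.43e-07; adjusted p = 0.0873 with an estimated correlation). MVD, MSMO1, HMGCS1 and DHCR7 had log2 fold changes of 2.21 ± 0.10, 1.37 ± 0.05, 1.29 ± 0.07 and 1.15 ± 0.05. Immediate early genes were higher in 11 of 14 and lower in 2 (12 and 2 adjusted over the list alone). With a median of 1.29, this list passed at an adjusted p = 4.25e-05 (adjusted p = 0.0873 with an estimated correlation). EGR1 went from 6874 ± 3.11 to 19422 ± 1329 and KLF6 from 857 ± 43.4 to 4705 ± 9.12. The immediate early list shares ATF3 with the integrated stress response list, and JUNB and IER3 with the NF-kB list. It was not tested without them. NF-kB targets were higher in 10 of 15 and lower in 2, the same adjusted over the list alone (median 0.58, adjusted p = 0.0115; adjusted p = 0.158 with an estimated correlation). They included the cytokines CXCL8 (93.8 ± 27.9 to 1119.6 ± 72.7) and IL6 (197 ± 41.6 to 763 ± 127). Genes listed as p53 targets were higher in 9 of 16 and lower in 1, the same adjusted over the list alone (median 0.27, adjusted p = 0.00627; adjusted p = 0.158 with an estimated correlation). K562 cells are known to lack functional p53. The cell cycle inhibitor CDKN1A went from 910.2 ± 102 to 6204 ± 243. TNFRSF10B, GADD45A and CCNG1 had log2 fold changes of 1.61 ± 0.08, 1.10 ± 0.06 and 0.55 ± 0.05. GDF15 had a value of -0.02 ± 0.43 by the probe set chosen, which read 77.0 ± 11.8 untreated, while allowing an _x_at probe set gave 3.42 with an adjusted p of 2.40e-10.

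The list of MYC and ribosome synthesis genes fell at 50 uM, 13 of 15 lower and 0 higher, the same adjusted over the list alone. Their median change was -0.79 (adjusted p = 5.13e-08; adjusted p = 0.0873 with an estimated correlation). POLR1B, a catalytic subunit of RNA polymerase I, went from 2808 ± 16.4 to 721 ± 72.3. NOP16, NOLC1 and nucleolin (NCL) had log2 fold changes of -1.64 ± 0.08, -1.50 ± 0.06 and -0.79 ± 0.05. DNA replication and E2F target genes were lower in 19 of 31 and higher in 4, the same adjusted over the list alone (median -0.42, adjusted p = 0.000311; adjusted p = 0.0873 with an estimated correlation). Log2 fold changes placed the uracil glycosylase UNG at -1.64 ± 0.11, POLE2 at -0.91 ± 0.08, MCM3 at -0.80 ± 0.06 and PCNA at -0.60 ± 0.05. The ribonucleotide reductase subunit RRM2 read 14656 ± 537 untreated and 14515 ± 402 at 50 uM and was not called. Respiratory chain and iron-sulphur protein genes were lower in 13 of 23 and higher in 1, the same adjusted over the list alone, by small amounts (median -0.15, adjusted p = 0.00167; adjusted p = 0.392 with an estimated correlation). NDUFS3 had a log2 fold change of -0.69 ± 0.06 and CYC1 of -0.48 ± 0.05.

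Iron handling genes moved both ways, 6 higher and 3 lower of 20 (median -0.01, camera adjusted p = 0.760). With 47.0% of all genes tested called at 50 uM, such counts alone do not set a list apart. The transferrin receptor TFRC went from 23073 ± 346 to 40920.2 ± 170.1, with a log2 fold change of 0.83 ± 0.04. NCOA4, the receptor for autophagy of ferritin, and the mitochondrial iron importer SLC25A37 were higher by 0.73 ± 0.05 and 0.57 ± 0.06. The iron exporter SLC40A1 (ferroportin) went from 3419 ± 136 to 1204 ± 37.2. The ferritin light chain FTL was called at 0.17 ± 0.05. This call ended with each untreated or 50 uM array left out and under both other scalings, and the value was -0.02 under quantile normalization. In the mTOR pathway list 9 of 24 were higher and 5 lower (adjusted p = 0.436). Besides DDIT4, SESN2, SESN3 and RICTOR were higher (2.51 ± 0.14, 1.52 ± 0.17 and 0.72 ± 0.07). MTOR itself was called lower at -0.35 ± 0.12 (adjusted p = 0.0342), but not with any single untreated or 50 uM array left out. TSC2 was 0.11 ± 0.14, not called. G1 cyclins and CDK inhibitors were higher in 7 of 14 and lower in 2 (adjusted p = 0.0969; adjusted p = 0.0464 without the filter), with CDKN1C at 1.26 ± 0.08 and cyclin D1 (CCND1) at 0.59 ± 0.09. The BCL2 family and caspase list had 6 higher and 3 lower of 15 (adjusted p = 0.356), among them PMAIP1 (NOXA), from 791 ± 29.4 to 4748 ± 284. No shift of the list passed the test for glycolysis (7 higher and 5 lower of 16, adjusted p = 0.473), mitosis (4 and 4 of 26, adjusted p = 0.773), or DNA damage response and repair (4 and 4 of 15, adjusted p = 0.354). The same was true of haem synthesis (5 and 2 of 10, adjusted p = 0.469), NRF2 targets (5 and 5 of 14, adjusted p = 0.811) and metallothioneins and zinc (0 and 2 of 8, adjusted p = 0.760). Within these lists ALDOC was at 1.60 ± 0.07, CCNB1 at -0.87 ± 0.06, H2AX at -1.23 ± 0.07, CPOX at 1.24 ± 0.11, PRDX1 at -0.96 ± 0.06 and the zinc exporter SLC30A1 at -1.20 ± 0.14. Medians and means differed in sign for iron handling (-0.0057 and 0.01), mitosis (-0.0066 and 0.0073), NRF2 targets (-0.02 and 0.20) and metallothioneins and zinc (0.07 and -0.05, the median turning negative under both other scalings).

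Lineage markers at 50 uM did not shift as lists. Globins and erythroid markers had 4 higher and 3 lower of 18 (adjusted p = 0.763), with embryonic globin HBE1 higher (20533 ± 584 to 29499 ± 186) and the transcription factors NFE2 and KLF1 lower (-1.09 ± 0.08 and -0.67 ± 0.09). Megakaryocyte markers had 4 higher and 0 lower of 7 (adjusted p = 0.0592), including CD9, GP6 and ITGA2B at 1.84 ± 0.18, 1.54 ± 0.14 and 1.15 ± 0.11. The list's adjusted p was 0.0410 without untreated replicate 2 and 0.0257 with median centring. Markers of other cell types were also tested. The myeloid and monocyte list had 1 higher and 1 lower of 5 (adjusted p = 0.9997, direction down with a median of 0.27), the lymphoid list 2 and 0 of 4 (adjusted p = 0.507), and the fibroblast and epithelial list 1 and 1 of 7 (adjusted p = 0.811). LYZ was lower at -0.90 ± 0.09 and EPCAM at -0.89 ± 0.07. These changes stood beside the higher ACTB 3' to 5' ratio of the treated arrays, while that of GAPDH was 1.30 both untreated and at 50 uM.

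**Figure D1:**
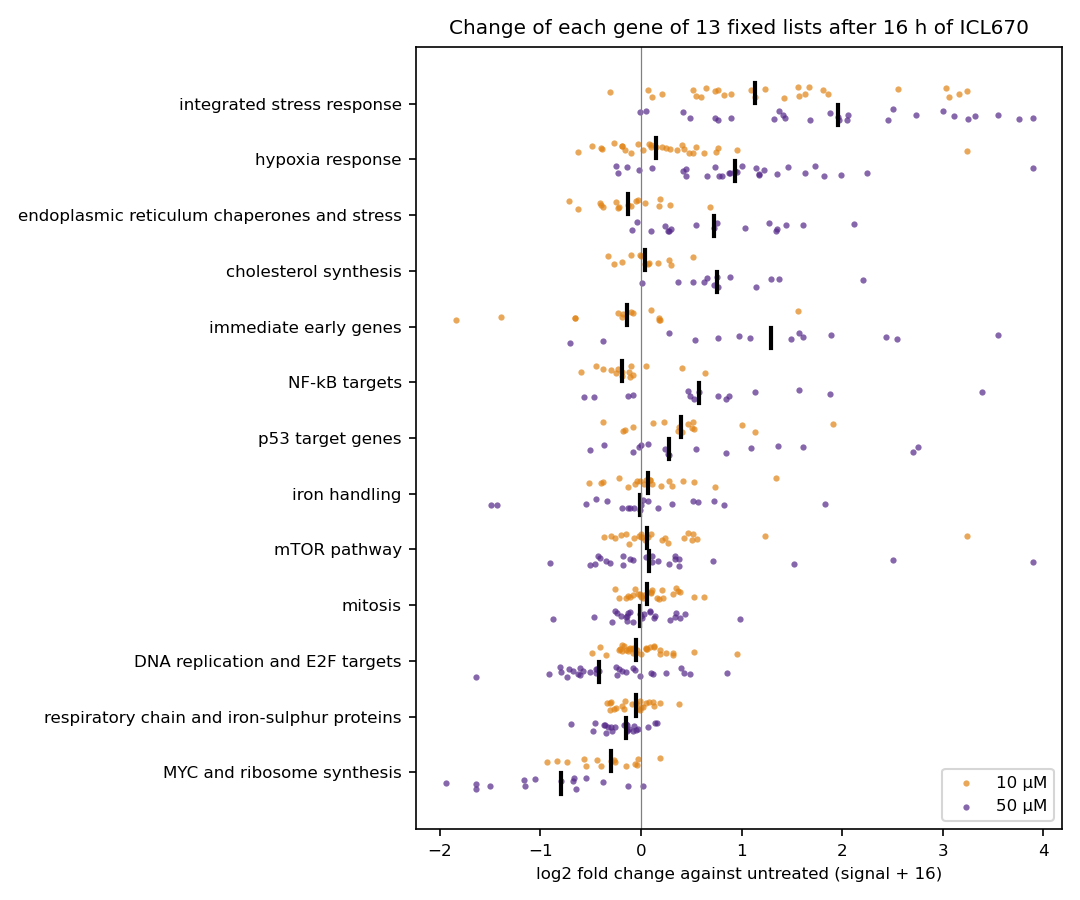
Log2 fold changes against untreated (horizontal axis, on signal + 16) of the tested genes of 13 lists fixed beforehand, 1 point per gene, for 10 uM (orange) and 50 uM (purple), with the list's median as a black bar. Medians of the integrated stress response list are 1.13 at 10 uM and 1.96 at 50 uM, and those of the hypoxia list 0.15 and 0.94.

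The comparison of 10 uM with the same untreated arrays asks what the lower dose changes. The largest rises were PDK4 (7.15 ± 8.13 to 309.8 ± 9.76), DDIT4 (1121 ± 192 to 10679 ± 97.9, log2 fold change 3.24 ± 0.09, adjusted p = 1.47e-08 by limma with Benjamini-Hochberg adjustment), the folate enzyme ALDH1L2 (3.16 ± 0.22) and the glutathione-degrading enzyme CHAC1 (3.06 ± 0.27). PHGDH (3.04 ± 0.07), INHBE (2.90 ± 0.16), MS4A4A (2.82 ± 0.09), CFAP95 (2.58 ± 0.11), ASNS (2.56 ± 0.06) and YPEL3 (2.53 ± 0.22) followed. PDK4, ALDH1L2 (32.5 ± 1.20), CHAC1 and YPEL3 were below the filter level untreated, so the sizes and ranks of their rises are uncertain. Of the largest falls, DHRS2 (1251 ± 144 to 163 ± 15), PRG2 (4369 ± 186 to 886 ± 108) and NEFH (1839 ± 149.6 to 466 ± 32.3) were well above the filter level of 59.5 before treatment. The other 7, CDC42EP2, PALM3, MVB12B, PCDH12, XIRP1, LOC100310756 and PRDM11, were dim, with untreated signals from 126 to 207 and 10 uM signals under the filter level. Altogether 1804 genes were called higher and 1510 lower, 3314 together (27.8% of the genes tested), of which 254 and 55 changed at least 2-fold. With median centring the split was 1286 higher and 1778 lower. The total was 2022 without untreated replicate 1, 2044 without untreated replicate 2 and 2563 without replicate 1 at 10 uM, the array with the conflicting treatment label. The calls of CDC42EP2, PALM3, LOC100310756 and PRDM11 each ended with at least 1 array left out, and that of MVB12B with probe sets averaged (-0.48, adjusted p = 0.445).

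Integrated stress response genes rose at 10 uM in 23 of 27 with 0 lower (24 and 0 adjusted over the list alone). The median was 1.13 (adjusted p = 9.59e-22; adjusted p = 0.361 with an estimated correlation). In the list of MYC and ribosome synthesis genes 8 of 15 were lower and 1 higher at 10 uM (9 and 1 adjusted over the list alone). The 1 called higher was MYC itself, a transcription factor gene named here after its values were seen, at 0.19 ± 0.06 (adjusted p = 0.0267), while it was lower at 50 uM (-0.38 ± 0.06). Its call at 10 uM ended without untreated replicate 2 (adjusted p = 0.223), without replicate 2 at 10 uM (adjusted p = 0.0867), with median centring (adjusted p = 0.227), without the filter (adjusted p = 0.0692) and without the intensity trend (adjusted p = 0.178). The list's median was -0.29 (adjusted p = 9.58e-05; adjusted p = 0.361 with an estimated correlation), with POLR1B at -0.74 ± 0.10 and NOP16 at -0.94 ± 0.08. The p53 target list had 9 higher and 1 lower of 16, the same adjusted over the list alone (median 0.40, adjusted p = 0.00653; adjusted p = 0.361 with an estimated correlation). CDKN1A was at 1.14 ± 0.09 and CCNG1 at 0.52 ± 0.05. Haem synthesis genes were higher in 6 of 10 and lower in 0, the same adjusted over the list alone (median 0.35, adjusted p = 0.0407; adjusted p = 0.361 with an estimated correlation), with CPOX at 0.59 ± 0.11. Without untreated replicate 1 the adjusted p was 0.0699, without replicate 1 at 10 uM it was 0.0847, and with the stricter filter it was 0.0964. Across arrays left out, the number of lists called at 10 uM was 7 without replicate 2 at 10 uM, against 4 with all arrays. The hypoxia list did not pass (9 higher and 5 lower of 29, median 0.15, adjusted p = 0.138). VEGFA was higher at 0.52 ± 0.05 and BNIP3L at 0.96 ± 0.08, SLC2A3 was lower at -0.19 ± 0.05, and NDRG1 was 0.10 ± 0.18, not called. Endoplasmic reticulum genes were lower in 6 of 17 and higher in 1 (7 and 2 adjusted over the list alone; median -0.13). They did not pass as a list (adjusted p = 0.0751), but did with median centring (adjusted p = 0.0496), without the filter (adjusted p = 0.0324) and without untreated replicate 2 (adjusted p = 0.0356). HSPA5 was lower at -0.38 ± 0.05, and the 1 gene called higher was HERPUD1 at 0.69 ± 0.08. TFRC went from 23073 ± 346 to 38407 ± 625, at 0.73 ± 0.04. TSC2 was higher at 0.47 ± 0.14, a call that ended without either untreated array and without replicate 2 at 10 uM. CCND1 was lower at -0.44 ± 0.09. Other lists that did not pass at 10 uM passed under some settings. G1 cyclins and CDK inhibitors (adjusted p = 0.0751) passed upward with quantile normalization (adjusted p = 0.0216), without the filter (adjusted p = 0.0324) and without replicate 2 at 10 uM (adjusted p = 0.0470). Respiratory chain genes passed downward with median centring (adjusted p = 0.0293) and without replicate 2 at 10 uM (adjusted p = 0.00744), and megakaryocyte markers passed upward with the stricter filter (adjusted p = 0.0217). Glycolysis passed downward with median centring (adjusted p = 0.0478), without the filter (adjusted p = 0.0468) and without replicate 2 at 10 uM (adjusted p = 0.00519). The ACTB 3' to 5' ratio was also higher at 10 uM than untreated, while that of GAPDH was 1.33 at 10 uM and 1.30 untreated.

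**Figure D2:**
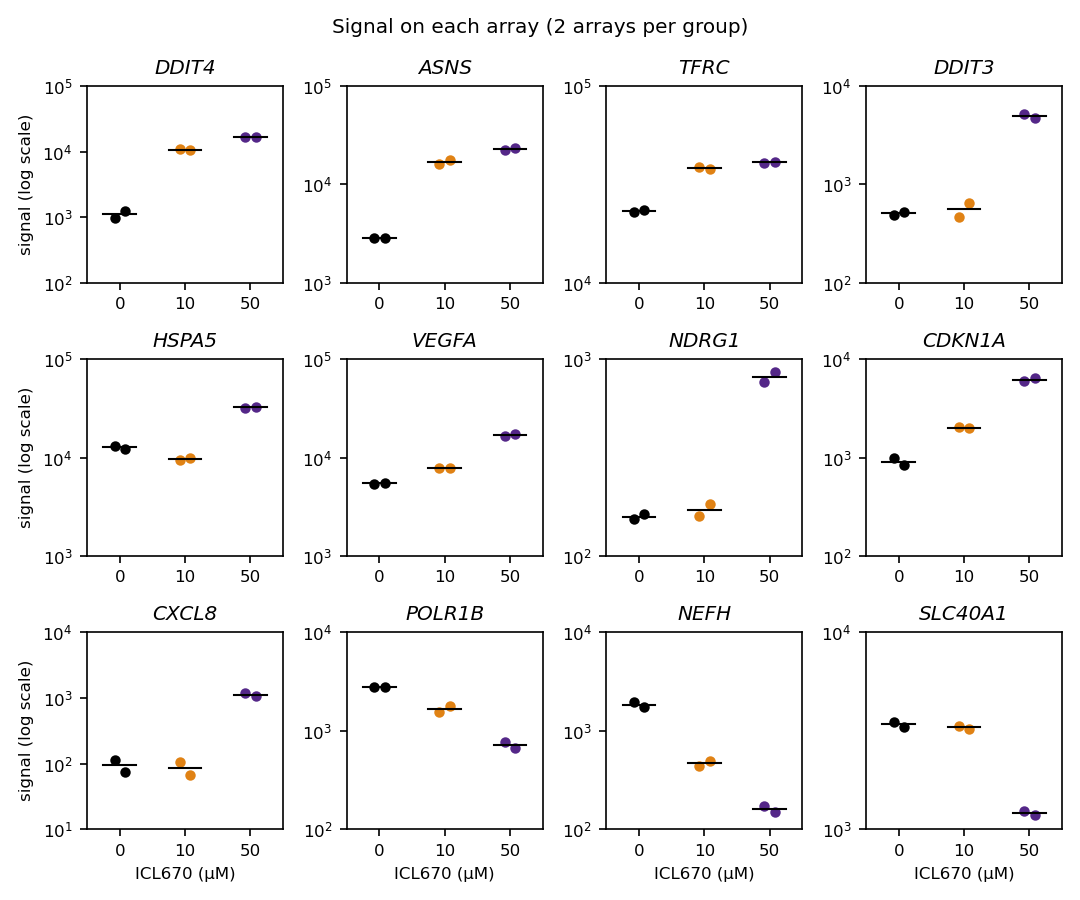
Signal on each of the 6 arrays (vertical axis, log scale) against the ICL670 dose in uM for 12 genes, with the mean of the 2 arrays of a group as a horizontal line. ASNS and DDIT4 are raised at 10 uM, while DDIT3, NDRG1 and CXCL8 at 10 uM lie near the untreated arrays and are raised at 50 uM.

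The direct comparison of 50 with 10 uM tests where the doses differ. The largest rises from 10 to 50 uM were XIRP1 (34.5 ± 5.59 to 899 ± 255), the transcription factor subunit FOS (12.6 ± 11.8 to 348 ± 52.0), CXCL8 (3.51 ± 0.26) and PHLDA1 (3.35 ± 0.13). The transcription factor DDIT3 (CHOP) went from 556 ± 132 to 4967 ± 287, a log2 fold change of 3.14 ± 0.14 (limma with Benjamini-Hochberg adjustment, adjusted p = 2.05e-07). The interferon-inducible genes OASL (3.03 ± 0.57) and IFIT3 (2.60 ± 0.21), the growth factor HBEGF (2.48 ± 0.56), arginase ARG2 (2.47 ± 0.08) and C11orf96 (2.38 ± 0.07) were also among them. At 10 uM XIRP1, FOS and HBEGF (23.6 ± 23.1) were below the filter level, so the sizes of their rises are uncertain. Among the largest falls, the globin gene HBQ1 went from 3139.6 ± 247 to 782 ± 27.4 and CAVIN2 from 3320 ± 364 to 855 ± 68.1. The other 8, DOCK8-AS1, MPND, CBR3-AS1, AKR1C3, RIMKLB, SMC5-DT, OOEP and LOC101927166, ended below the filter level at 50 uM, and the calls of SMC5-DT, OOEP and LOC101927166 ended with at least 1 array left out. That of RIMKLB ended with _x_at probe sets allowed (-0.26, adjusted p = 0.365). In total 1774 genes were higher and 2300 lower at 50 than at 10 uM, 4074 together (34.2% of the genes tested).

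Endoplasmic reticulum chaperone and stress genes were higher at 50 than at 10 uM in 17 of 17, the same adjusted over the list alone (median 0.67, adjusted p = 2.00e-14). The hypoxia list had 20 of 29 higher and 0 lower (21 and 0 adjusted over the list alone; median 0.65, adjusted p = 5.32e-12). Cholesterol synthesis had 12 of 13 and 0, the same adjusted over the list alone (median 0.78, adjusted p = 4.21e-11), and the immediate early list 12 of 14 and 1, again the same (median 1.54, adjusted p = 1.32e-09). These 4 lists also passed with an estimated correlation, each at an adjusted p of 0.0429. The integrated stress response list had 18 of 27 higher and 0 lower (20 and 0 adjusted over the list alone; median 0.40, adjusted p = 2.30e-09; adjusted p = 0.139 with an estimated correlation). NF-kB targets were higher in 9 of 15 (11 adjusted over the list alone; adjusted p = 1.64e-05; adjusted p = 0.0725 with an estimated correlation). The oxygenases, some of them also in the hypoxia list, were higher in 12 of 27 and lower in 2 (camera adjusted p = 0.000585, and adjusted p = 0.0886 with an estimated correlation). Glycolysis genes were higher in 10 of 16 and lower in 1 (adjusted p = 0.000737; adjusted p = 0.334 with an estimated correlation). DNA replication genes were lower in 19 of 31 and higher in 1 (22 and 1 adjusted over the list alone; adjusted p = 1.34e-06; adjusted p = 0.0606 with an estimated correlation). Ribosome synthesis genes were lower in 13 of 15 (adjusted p = 4.26e-07; adjusted p = 0.0886 with an estimated correlation) and respiratory chain genes in 7 of 23 (adjusted p = 0.0181; adjusted p = 0.447 with an estimated correlation). The respiratory chain call ended without replicate 2 at 10 uM (adjusted p = 0.0772), without replicate 1 at 50 uM (adjusted p = 0.0530) and with the stricter filter (adjusted p = 0.0666). TFRC differed by 0.09 ± 0.04 between the doses and was not called (limma adjusted p = 0.103). The difference was 0.11 without replicate 1 at 10 uM. TFRC was bright at both doses, against a highest signal of 66306 on the arrays. Whether bright signals were compressed was not tested for this gene, so the small difference does not show a plateau. DNA damage response genes (adjusted p = 0.0548) passed downward between the doses with quantile normalization (adjusted p = 0.0480), without the filter (adjusted p = 0.00809) and without replicate 2 at 10 uM (adjusted p = 0.0334), and p53 targets (adjusted p = 0.109) passed upward with the stricter filter (adjusted p = 0.0218).

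Both doses were set against the same 2 untreated arrays. At both, 1314 genes were higher and 1173 lower, 2487 in the same direction. Independent lists of these sizes share 780.1 (429.7 higher and 350.4 lower). Simulated groups in which no gene changed, against shared controls, share 0.06 (mean of 100 simulations). With no gene changed almost none is called, so this count was bound to be small. It cannot show how much overlap shared controls add. Opposite directions were called for 125 genes, 70 lower at 10 and higher at 50 uM and 55 the other way. Independent lists would give 778.2. The simulated groups gave 0, which for the same reason is no test. The log2 fold changes at the 2 doses correlated across genes, which are not independent replicates, at Pearson r = 0.64 and Spearman rho = 0.62. Of the genes, 73.0% had the same sign. In the simulated groups, which hold noise alone, Pearson r was 0.50 and 66.6% had the same sign. Those values are no baseline for data in which genes change. The covariance of the log2 fold changes was 0.174 against 0.0248 simulated, a difference of 0.149. Setting each dose against its own single untreated array, an alternative chosen after seeing the data, gave a covariance of 0.146 or 0.145, depending on which array served which dose. It gave 1457 or 1439 genes in the same direction and 58 in opposite directions either way. Each dose then has only 1 control, and part of the excess in counts with both untreated arrays shared may come from the shared controls. Of the covariance of 0.174, 0.146 or 0.145 remained without a shared array. The spread between the 2 untreated arrays therefore does not account for most of it. That these values lie near the difference of 0.149 is no separate test. Each takes an estimate of the untreated arrays' spread off the same covariance. A departure common to both untreated arrays would remain in each value and cannot be seen here. Of the genes higher at both doses, 422 were higher still at 50 than at 10 uM, 839 showed no call between the doses and 53 were lower at 50 uM. Of those lower at both, 638 were lower still at 50 uM, 521 showed no call between the doses and 14 were higher at 50 uM. The count in the same direction was 1586 without untreated replicate 1 and 1624 without untreated replicate 2.

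**Figure D3:**
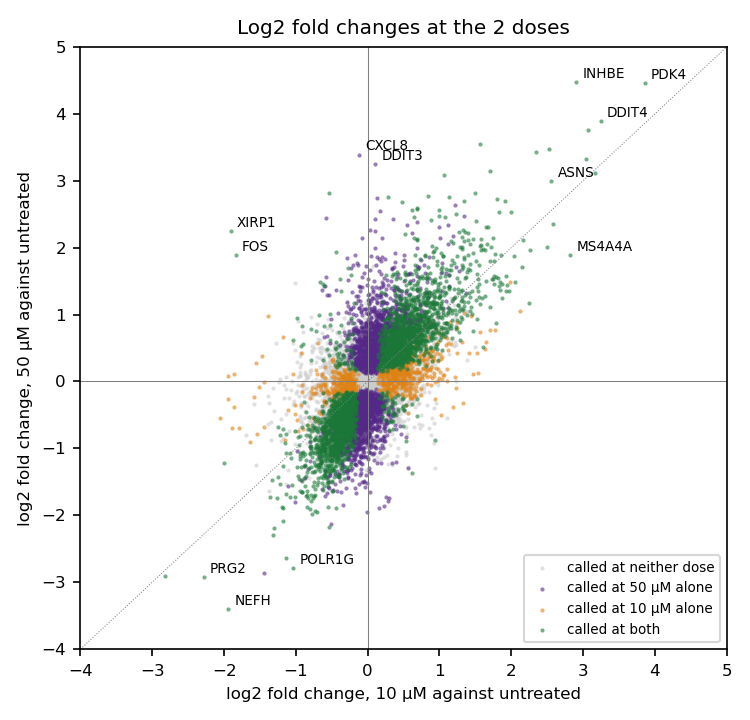
Log2 fold change of each of the 11903 genes against untreated at 10 uM (horizontal axis) and at 50 uM (vertical axis), coloured by the doses at which it was called, with a dotted line of equal change. PDK4, DDIT4 and ASNS lie high at both doses, CXCL8 and DDIT3 high at 50 uM alone, and XIRP1 and FOS on opposite sides at the 2 doses.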

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

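Of the tests in this part, those of the dose of ICL670, of bright signals, of dim regulators, of the 2 gene classes and of ribosomal RNA carry-over were written down only after values that bear on them had been seen; those of scaling and of single arrays were written beforehand.

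The first results stand out because the effect differed between the doses by the direct comparison. In 4 lists the median log2 fold change was below 0 at 10 uM and above 0 at 50 uM, and the list passed between the doses: the median change from 10 to 50 uM was 0.67 for endoplasmic reticulum chaperone and stress genes, 1.54 for immediate early genes, 0.63 for NF-kB targets and 0.22 for glycolysis. Between the doses NF-kB targets (adjusted p = 0.0725) and glycolysis (adjusted p = 0.334) did not pass with an estimated correlation. None of the 4 lists passed at 10 uM against untreated in the setting reported, but 2 did under other settings, both pointing down. Glycolysis passed with median centring (adjusted p = 0.0478), without the filter (adjusted p = 0.0468) and without replicate 2 at 10 uM (adjusted p = 0.00519), and the endoplasmic reticulum genes with median centring (adjusted p = 0.0496), without the filter (adjusted p = 0.0324) and without untreated replicate 2 (adjusted p = 0.0356). By gene, 125 were called in opposite directions. Of these, 70 were lower at 10 and higher at 50 uM, such as XIRP1, FOS and HSPA5, and 55 were higher at 10 and lower at 50 uM, such as HBQ1. The latter include MYC, whose call at 10 uM ended under several settings.

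For the endoplasmic reticulum genes, 6 called lower at 10 uM and 14 higher at 50 uM, scaling is argued against as the cause: under the other scalings at least 6 were called lower at 10 uM and at least 11 higher at 50 uM. Without the intensity trend 3 were lower at 10 uM. A single array as the source is argued against as well, since the highest list median at 10 uM with 1 array left out was -0.082 and the lowest at 50 uM was 0.67, although the former is small. That 17 of 17 genes were called higher at 50 than at 10 uM is the difference that drew attention to this list, so it is no separate test of a dose effect of ICL670. The rise of the list at 50 uM passed its test against untreated and against 10 uM, but with an estimated correlation only that against 10 uM did (adjusted p = 0.0429, against adjusted p = 0.0873), and whether the list falls at 10 uM depends on the setting and stays open.

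Within the integrated stress response list, 16 genes of amino acid metabolism, transport and tRNA charging had a median log2 fold change of 1.496 at 10 uM and 1.93 at 50 uM, and 9 transcription factors and regulators 0.55 and 1.96. Saturation of bright probe sets is argued against by the median signal of the former at 10 uM, 6208, against a highest signal of 66306 on the arrays. Regulators too dim to show a rise at 10 uM are argued against by their median untreated signal of 531.1, against a filter level of 59.5. Both medians speak for a class as a whole and not for its brightest or dimmest members. The median rise from 10 to 50 uM was larger by 0.88 for the regulators (two-sided permutation p = 0.0017, 100000 permutations of the class labels). The classes were drawn up after some of these values had been seen and genes are not independent, so this decides nothing, and a different dose response of the classes stays open as a hypothesis.

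RNA45SN5, the 45S ribosomal RNA precursor, a gene chosen after its values were seen, was called lower at 10 uM (log2 fold change -1.18, adjusted p = 0.00843) and at 50 uM (-0.71, adjusted p = 0.0497). Without untreated replicate 2, which had the highest 18S ribosomal RNA signals, the value at 10 uM was -0.997 and the call ended (adjusted p = 0.0832, standard error 0.346 against 0.269), and over the arrays left out its adjusted p ran from 0.00339 to 0.0832. Leaving out that array does not remove carry-over of ribosomal RNA that the other untreated array may share, since 3 of 4 ribosomal RNA controls were higher on both untreated arrays than on both 10 uM arrays, such as that for 28S (4193 and 5070 against 2927 and 2518). At 50 uM the call ended with 4 of the 6 arrays left out in turn (adjusted p from 0.0513 to 0.344), and the value was -0.34 without replicate 2, leaving replicate 1 with its higher ribosomal RNA controls, and -1.09 without replicate 1. Carry-over therefore stays open, and no biological explanation was tested for this gene.

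Outside the gene test, 824 of 3550 kept probe sets with no gene symbol here and 546 of 1176 with several symbols were called changed at 50 uM against untreated. The latter include 3 probe sets shared by the fetal globin genes HBG1 and HBG2, called higher at 50 uM with adjusted p of 0.00342, 0.00342 and 0.00118. Their mean signals by group, from 43196 to 57911, lay near the highest signal on the arrays, 66306, so the sizes of these changes are uncertain and are not given.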

How the results depend on the processing

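The counts at 50 uM against untreated, 10 uM against untreated and 50 against 10 uM stayed within 1.5 times of 5597, 3314 and 4074 under the other scalings, pseudocounts, filters, rules for choosing a gene's probe set and robust variances, and with only the 2 groups compared. They moved further with other units or thresholds. Testing all 54613 non-control probe sets without a filter gave 9023 at 50 uM. Testing all 27306 probe sets above the filter, an alternative chosen after seeing the data, gave 10333, 5282 and 7028. Both alternatives count probe sets, not genes, and 5931 genes had more than 1 probe set above the filter. These counts therefore do not compare directly with those of the 11903 genes. A log2 fold change of at least 1 left 1076, 309 and 411. Without the intensity trend the count at 10 uM was 1823; the cause was not tested. Leaving out 1 array, with the lone array of its group assumed to vary like the others, gave 4533 to 5665, 2022 to 3191 and 3049 to 3838 genes, and 1586 to 2222 genes in the same direction at both doses; fewer arrays carry less information. With each dose against its own untreated array, chosen after seeing the data, these were 1457 or 1439. Fewer controls then served each dose and none was shared between the doses. Which of these lowered the counts was not tested. The 26 lists gave 11, 4 and 11 calls. At 10 uM there were 7 with median centring and 7 without a filter, causes not tested, and with 1 array left out the lists called numbered 11 at 50 uM, 3 to 7 at 10 uM and 10 to 11 between the doses. With an estimated correlation, which rests on 3 residual degrees of freedom, 0, 0 and 4 lists were called by limma's camera, against 7, 3 and 9 at an unadjusted p under 0.05. For single lists, 587 results under other settings stayed on the same side of the threshold in the same direction, 13 newly passed and 24 no longer passed, the last number including the estimated correlation. With arrays left out these were 457, 6 and 5. For named genes they were 1264, 9 and 10 under other settings, with 5 turned in direction, and 1058, 8 and 38 with arrays left out. GDF15 turned direction: with _x_at probe sets allowed it was 3.42 at 50 uM and 1.45 at 10 uM, and with probe sets averaged 1.70 and 0.64, as another probe set was then read. FTL was -0.024 at 50 uM under quantile normalization, the cause not tested. The arrays share only a replicate number: same-numbered arrays deviated from their group means with correlations of 0.02, 0.01 and -0.01, and with the number as a replicate block the counts were 5519, 3203 and 3985 and the lists called 11, 4 and 11. Among named genes the block changed the call of RRM2 between the doses (-0.14, adjusted p = 0.0424) and no other. Signals near the filter level of 59.5 limit dim genes such as CDC42EP2 and OOEP, whose calls ended with each of 3 arrays left out.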

Other observations

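The tests on members not seen beforehand in this part were chosen only after the results for the full lists had been seen. The full lists themselves were drawn up after single genes had drawn attention to them.

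RNA polymerase I and III subunits, a list prompted by POLR1G and POLR1B, were lower in 13 of 18 and higher in 2 at 50 uM, with a median log2 fold change of -0.71. The camera p of 2.91e-05 gave an adjusted p = 6.78e-05 over the 7 added lists (adjusted p = 0.0707 with an estimated correlation). Of the 13 subunits neither in a fixed list nor among the largest changes looked at first, 8 were lower and 2 higher, with a median of -0.31. Their camera p of 0.0181 did not hold over the 4 such tests (adjusted p = 0.0726), so whether the fall extends to the subunits as a group stays open. Mitochondrial aminoacyl-tRNA synthetase genes were lower in 8 of 15 and higher in 0 at 50 uM (median -0.53, adjusted p = 0.00198; adjusted p = 0.0901 with an estimated correlation).

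Other groups did not pass beyond the genes that prompted them in the comparison where those genes were seen. Cytosolic aminoacyl-tRNA synthetases at 10 uM had 8 higher and 4 lower of 17, with a camera p of 0.00314 (adjusted p = 0.00549; adjusted p = 0.227 with an estimated correlation). The mitochondrial list had a camera p of 0.112 there and pointed down. The cytosolic list includes 4 genes already seen, and the other 13 had 4 higher and 4 lower, with a camera p of 0.485 (adjusted p = 0.485). Interferon-stimulated genes at 50 uM, prompted by IFIT3 and OASL, had 8 higher and 3 lower of 20, with a camera p of 0.181 (adjusted p = 0.212). Without those already seen, 6 of 18 were higher and 3 lower, with a camera p of 0.443 (adjusted p = 0.485). Tubulin genes at 50 uM, prompted by TUBB2B and TUBA1A, had 4 higher and 4 lower of 14, with a camera p of 0.75 (median -0.11 and mean 0.31). Without those already seen, 2 of 12 were higher and 4 lower, pointing down, with a camera p of 0.121 (adjusted p = 0.243). At 10 uM the full tubulin list had 3 higher and 7 lower of 14, with a median of -0.21. It passed downward there (camera adjusted p = 0.0378), but not with an estimated correlation (adjusted p = 0.195). Its members not seen beforehand were not tested at that dose.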
